A study of Mus musculus with 4 samples.

How the data were processed

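RNA from the hypothalamus of 30-week-old mice was sequenced in 4 libraries, 2 labelled wild type and 2 labelled Rai1 conditional knockout. Group and replicate letter (A or B) were taken from the sample titles, and all 4 columns of the table matched a title. The authors deposited 1 table of RPKM (reads scaled to the length of the gene model and the depth of the library) with a row per gene symbol and a column per library, per the file headers. Base calling with CASAVA 1.8.2, trimming with cutadapt 1.6 and alignment with TopHat2, for which no version is given, are named together with the mouse build mm9 per the submitters' processing notes, without their order or settings. The gene models are the RefSeq genes of mm9, per the deposited table's own label. The program that counted the reads, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads shared by overlapping genes, antisense partners or near-identical copies could therefore be split in ways that are not known.

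The RPKM of each gene move in steps, because they were made from whole reads. Comparing these steps between libraries gave the number of reads each library was divided by and the length of each gene model. That depth was 38.3 M reads for wild type A, 38.5 M for wild type B, 42.2 M for the library labelled knockout A and 47.6 M for the library labelled knockout B. Whole reads were recovered for 11223 of 11535 genes with a mean RPKM of at least 1 (97.3%), with a tolerance of 0.05 reads, and the median over these genes was 643 reads per library. On simulated values made from 6000 genes, of which 4055 had a mean RPKM of at least 1, the procedure recovered 97.7% of genes, and 99.7% of those had the exact reads. Recovered gene reads made up 33.6% and 33.2% of the depth in wild type A and B, and 29.5% and 31.9% in the libraries labelled knockout A and B. RPKM summed to 128957, 129288, 109436 and 121510 in the same order, so the deposited values were not brought to a common total over genes. Spread and tests below include counting error, which these reads make small for most genes, and the difference between libraries.

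The main comparison set the 2 libraries labelled knockout against the 2 wild-type libraries. Values were taken as log2(RPKM + 0.5) for genes with a mean RPKM of at least 1 over the 4 libraries, with no rescaling, and fitted with limma 3.58.1 in R 4.3.3 (moderated test, eBayes with a mean-variance trend, two-sided). Benjamini-Hochberg adjusted p under 0.05 over 11535 genes counted as a call. Fold changes on this scale understate the change of low genes. The fit has 2 residual degrees of freedom per gene and borrowed 15.3 prior degrees of freedom from the other genes. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333, so every call rests on that shared estimate of the spread. The labels do not say that the libraries of a group come from separate animals, so p-values measure only the spread between these libraries, which may be technical. The median log2 change of all genes was -0.12. Single-gene changes are therefore given relative to this median, while adjusted p refer to the values as deposited unless the rescaled fit is named.

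Gene lists were fixed, with the test and the alternatives, before the data were examined. There were 32 lists: Bdnf-TrkB signalling, feeding neuropeptides and receptors, magnocellular and neuroendocrine peptides, hypothalamic transcription factors, the circadian clock, immediate early genes, glucocorticoid-responsive genes, glutamatergic transmission, GABAergic transmission, monoaminergic neurons, cholesterol synthesis, oxidative phosphorylation, cytosolic ribosomal proteins, heat shock and the unfolded protein response, the interferon response, Smith-Magenis interval neighbours of Rai1, chromatin regulators, and markers of neurons, oligodendrocytes, their precursors, astrocytes, microglia, endothelium, meninges, ependyma, choroid plexus, pituitary, thalamus, striatum, cortex and hippocampus, blood and sex. Of their genes, 2 matched no symbol in the table. The 29 lists with at least 5 measured members were tested with camera (limma), which compares a list with the other genes, at a preset inter-gene correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. The alternative with an estimated correlation has only the 2 residual degrees of freedom of the fit, so hardly any list could pass it.

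Genes are named by a rule set at the same time: Rai1 and Bdnf; up to 12 genes of lowest p in each direction among those with an adjusted p under 0.05 and no overlap between groups, filled where fewer passed with the genes of lowest unadjusted p that had a log2 change of at least 0.5 and no overlap; for each list up to 4 members of lowest p and any member that passed with adjustment over the list alone; and chromosomal neighbours and sex-linked markers whatever their values. Any other gene is said to have been chosen after its values were seen.

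The comparison was repeated with pseudocounts of 0.1 and 1, no filter, a mean RPKM of at least 5, median-ratio scaling, quantile normalization, eBayes without the trend, robust eBayes, the replicate letter as a block, each library left out in turn, camera with an estimated correlation, fry, and a count at unadjusted p under 0.05 without overlap. A fit with the gene-length trend removed from each library (loess, span 0.3), which also centres each library and covers the 11223 genes with a recovered length, and a fit with voom weights on the recovered reads were added after seeing the data. Tested on simulated data for 11535 genes with the spread of the real fit, the main test recovered 87 of 90 tested genes changed by a log2 of 1 and 21 of 97 changed by 0.5, and 5 of its 113 calls were false. Of 100 genes changed at each size, the others fell below the filter on low values. In camera, a simulated list of 20 genes shifted together passed, and none of 20 unshifted lists reached the threshold before adjustment. The simulated genes were drawn independently, with no correlation between genes, no shift of all genes and no length trend. These simulations therefore do not give the rate of false calls in the real libraries, for genes or for lists. The reference annotation in use here is of another build than mm9 (GRCm38), so no coordinates are given. It served for gene order and as a guide to gene-model lengths. Recovery and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.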

Results

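The series profiled RNA from the hypothalamus, the brain region that controls feeding, body temperature, stress hormones and sleep, in 30-week-old mice, F1 of B6/FVB. Its stated purpose was to find genes regulated by Rai1. Rai1 (retinoic acid induced 1) encodes a chromatin-binding protein, and loss of a single copy of the human gene causes Smith-Magenis syndrome, a disorder with obesity and disturbed sleep. In the mice labelled knockout, Rai1 was to be deleted in adulthood with Ubc-CreERT2, a Cre recombinase that is expressed broadly and becomes active when tamoxifen is injected. The labels carry the same treatment text for the wild-type libraries and do not say whether wild-type mice carried Cre or received tamoxifen. There were 2 wild-type libraries and 2 libraries labelled knockout, with depths of 38.3, 38.5, 42.2 and 47.6 M reads. The table held 24176 genes, of which 4944 were listed at 0 in every library and 11535 were tested. Values are RPKM as mean ± SD with n = 2 libraries per group, and log2 changes are the libraries labelled knockout minus wild type, relative to the median of all genes.

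Rai1, the targeted gene, was higher in both libraries labelled knockout than in both wild-type libraries. Its level was 6.15 and 3.95 RPKM in wild type A and B (5.05 ± 1.56), and 18.7 and 8.03 RPKM in the libraries labelled knockout A and B (13.4 ± 7.56). These levels rested on 1770, 1141, 5931 and 2870 reads over a gene model of 7507 bp. The log2 change was 1.35 (SE 0.257, limma adjusted p = 0.0291), which goes against the label. All directions below therefore follow the labels and not a measured loss of Rai1. The table has 1 value per gene, so reads over the deleted part cannot be told from reads over the remaining exons. Rescaling the libraries ended the call (adjusted p = 0.11), and without library A of those labelled knockout the unshifted log2 change was 0.65 in place of 1.24.

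Bdnf, which encodes the growth factor BDNF that limits feeding, was lower in both libraries labelled knockout. It measured 2.38 ± 0.0224 RPKM in wild type and 1.19 ± 0.27 RPKM in the libraries labelled knockout (609, 620, 282 and 440 reads), a log2 change of -0.66 (SE 0.167, limma adjusted p = 0.0346). Of the 21 measured genes of Bdnf-TrkB signalling, 2 fell, both over all genes and adjusted over the list alone. The other was Vgf, a secreted neuropeptide precursor induced by BDNF, at 21.3 ± 2.29 and 11.6 ± 0.952 RPKM (limma adjusted p = 0.00649). The list as a whole had a median log2 change of -0.04 and did not pass (camera adjusted p = 0.444). The call of Bdnf ended with rescaling (limma adjusted p = 0.11) and without wild type A (0.0788), wild type B (0.116) or library A of those labelled knockout (0.0555). That of Vgf ended with rescaling (limma adjusted p 0.0506) and without wild type A (0.0727).

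**Figure D1:**
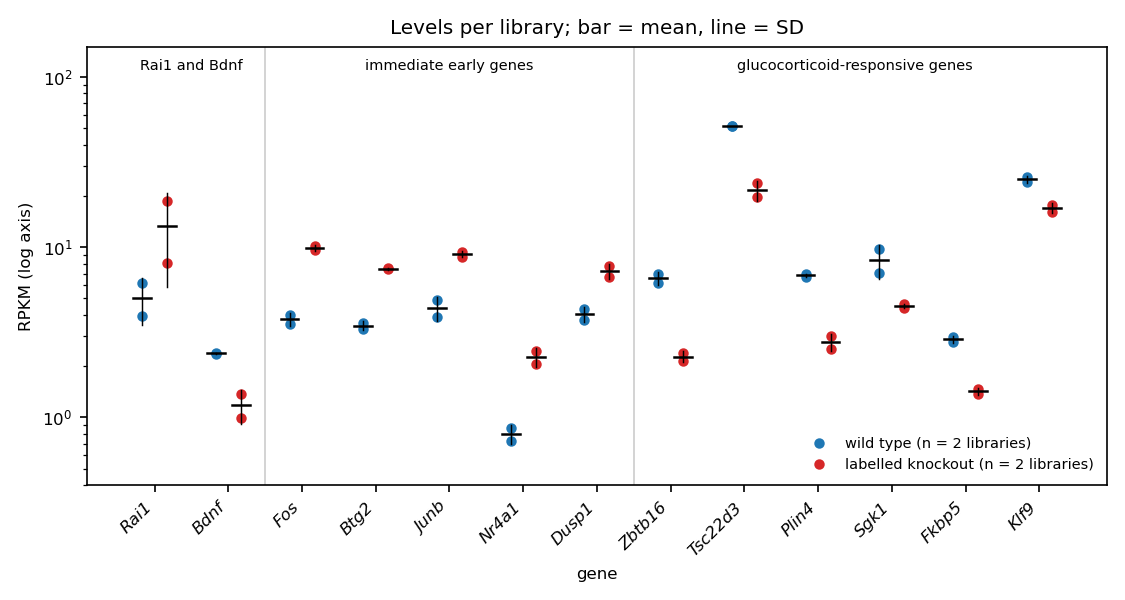
RPKM on a log axis in each library for Rai1, Bdnf, the 5 called immediate early genes and the 6 glucocorticoid-responsive genes that fell. Points are the 2 libraries of each group, thick bars their mean and thin lines the SD. Rai1 was higher in the libraries labelled knockout (18.7 and 8.03 RPKM) than in wild type (6.15 and 3.95 RPKM).

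Of 11535 genes tested, 9 were higher and 98 lower in the libraries labelled knockout as deposited. The 9 were Fos, Btg2, Junb, Nr4a1, Dusp1, Speer7-ps1, Leng8, Rai1 and Serpina3n. Fos, a subunit of the AP-1 transcription factor, rose from 3.76 ± 0.32 to 9.89 ± 0.415 RPKM (log2 change 1.41, SE 0.133, limma adjusted p = 0.000107). Leng8 rose from 8.35 ± 0.388 to 14.1 ± 2.81 RPKM, and Serpina3n, a protease inhibitor made by reactive astrocytes, from 32.8 ± 3.09 to 48.9 ± 5.63 RPKM. Speer7-ps1 is a pseudogene of a family of near-identical copies, so its reads are uncertain. Rescaling ended the call of Speer7-ps1 (limma adjusted p 0.0558). Without wild type A the calls of Speer7-ps1, Leng8 and Serpina3n ended (limma adjusted p 0.0976, 0.139 and 0.155), and without wild type B those of Leng8 and Serpina3n (0.0597 and 0.532). Among genes that did not pass, 5031410I06Rik, 2410021H03Rik and Olfr692 were next, with limma adjusted p of 0.0603, 0.07 and 0.0798.

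The 12 genes of lowest p that fell were Zbtb16, Tsc22d3, Nts, Plin4, Shox2, Ramp3, Vgf, Hr, Tmem11, Slitrk6, Uqcc2 and Pdp1. Nts, the precursor of the neuropeptide neurotensin, which reduces feeding, fell from 6.2 ± 0.666 to 2.34 ± 0.268 RPKM (log2 change -1.12, SE 0.144, limma adjusted p = 0.000324). Shox2, a homeobox transcription factor, fell from 4.21 ± 0.765 to 1.78 ± 0.239 RPKM, and Hr, a nuclear receptor corepressor, from 4.61 ± 0.511 to 2.16 ± 0.309 RPKM. Pdp1, a mitochondrial phosphatase that activates pyruvate dehydrogenase, fell from 39.5 ± 3.54 to 23.7 ± 1.27 RPKM. Tmem11 and Uqcc2, which act in the organisation of mitochondrial membranes and the assembly of respiratory complex III, fell by 0.68 and 0.74 on the log2 scale. Without wild type B the calls of Slitrk6, Uqcc2 and Pdp1 ended (limma adjusted p 0.0784, 0.0621 and 0.214).

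The number and split of the calls depended on scaling. After each library was rescaled by its median ratio, limma called 7 higher and 6 lower genes (46.2% lower, against 91.6% as deposited), and these 13 were all among the 107 called as deposited: Fos, Btg2, Junb, Nr4a1, Dusp1, Leng8 and Serpina3n higher, and Tsc22d3, Zbtb16, Nts, Plin4, Shox2 and Tmem11 lower. The count also moved with single libraries: 14 higher and 52 lower without wild type A, 12 and 41 without wild type B, 49 and 296 without library A and 43 and 1097 without library B of those labelled knockout.

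Immediate early genes, which neurons switch on within minutes of being active, were higher in the libraries labelled knockout. Of 15 measured members, 5 rose over all genes and 6 adjusted over the list alone, and none fell. Btg2, an antiproliferative gene, rose from 3.46 ± 0.202 to 7.46 ± 0.0755 RPKM, Junb, an AP-1 subunit, from 4.36 ± 0.704 to 9.08 ± 0.378 RPKM, and the nuclear receptor gene Nr4a1 from 0.799 ± 0.101 to 2.26 ± 0.285 RPKM. Their log2 changes were 1.13, 1.1 and 1.2, with limma adjusted p of 0.0013, 0.00298 and 0.00649. Dusp1, a phosphatase that switches off MAP kinases, rose from 4.04 ± 0.402 to 7.21 ± 0.725 RPKM, and that call ended without wild type B (limma adjusted p 0.139). Arc, a regulator of synaptic strength, measured 3.85 ± 0.758 and 5.68 ± 0.0886 RPKM and passed over the list alone (limma adjusted p over all genes 0.0978). The list of immediate early genes had a median log2 change of 0.27 (camera adjusted p = 3.2e-13; adjusted p = 0.398 with an estimated correlation). That median was 0.08 without the filter on low values, 1.02 with a mean RPKM of at least 5 and 0.52 without wild type A. The list passed camera without the filter and with the mean of at least 5. That mean covers all 4 libraries, so genes that rose pass it more easily. Fos, Btg2, Junb and Dusp1 were below 5 RPKM in wild type and passed through their levels in the libraries labelled knockout. The median of 1.02 is therefore partly a result of the filter. In the main fit, Nr4a1 was below 1 RPKM in wild type. It passed the mean of at least 1 through its levels in the libraries labelled knockout. The median of 0.27 also depends on its filter, since it was 0.08 without one.

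Glucocorticoid-responsive genes, which the stress hormone corticosterone induces through its receptor, were lower in the libraries labelled knockout. Of 16 measured members, 6 fell and 1, Dusp1, rose over all genes, and 9 fell and 1 rose adjusted over the list alone. Tsc22d3 (GILZ), a mediator of the anti-inflammatory action of glucocorticoids, fell from 51.3 ± 0.0273 to 21.7 ± 2.92 RPKM, and Zbtb16, a zinc-finger transcription factor, from 6.58 ± 0.59 to 2.28 ± 0.173 RPKM. Both log2 changes were beyond -1.1 (-1.11 and -1.23), with a limma adjusted p of 0.000107 each. Plin4, a lipid droplet protein, fell from 6.82 ± 0.135 to 2.77 ± 0.328 RPKM, the kinase Sgk1 from 8.4 ± 1.91 to 4.51 ± 0.147 RPKM, and Fkbp5, a co-chaperone that dampens the receptor, from 2.87 ± 0.132 to 1.42 ± 0.0725 RPKM. Klf9, a transcription factor, fell by 0.43 on the log2 scale. Mt2, Arrdc2 and Mt1 passed over the list alone, with log2 changes of -0.50, -0.45 and -0.34. The list median was -0.39 (camera adjusted p = 5.65e-08; adjusted p = 0.398 with an estimated correlation). Without wild type A the median of the glucocorticoid-responsive genes was -0.25 and without library B of those labelled knockout -0.22, and the list passed camera both times. Rescaling ended the calls of Sgk1, Fkbp5 and Klf9 (limma adjusted p 0.0986, 0.0986 and 0.134), as did leaving out wild type A for Fkbp5 and Klf9 (0.0788 and 0.226) and wild type B for Sgk1 and Klf9 (0.249 and 0.455). Thalamic markers were also lower in the libraries labelled knockout, with a list median of -0.45.

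Markers of the thalamus, habenula and neighbouring diencephalon, structures that border the hypothalamus, were lower in the libraries labelled knockout. Of 15 measured members, 5 fell over all genes and 12 adjusted over the list alone, and none rose. Ramp3, a receptor accessory protein, fell from 6.74 ± 1.53 to 2.93 ± 0.687 RPKM, Prkcd, a protein kinase C of thalamic relay neurons, from 7.46 ± 1.57 to 3.39 ± 1.3 RPKM, and Slitrk6 from 5.82 ± 1.53 to 2.67 ± 0.482 RPKM. The transcription factor genes Zic1 and Rora fell by 0.53 and 0.51 on the log2 scale. Tcf7l2, Synpo2, Rgs16, Plekhg1, Vav3, Lef1 and Pvalb passed over the list alone, with log2 changes between -0.52 (Tcf7l2) and -0.32 (Lef1). The list median was -0.45 (camera adjusted p = 6.75e-09; adjusted p = 0.398 with an estimated correlation). None of the 5 calls held after rescaling (limma adjusted p between 0.0789 for Slitrk6 and 0.188 for Rora). Leaving out wild type A ended those of Zic1 and Rora (0.156 and 0.0672), and wild type B those of Slitrk6, Zic1 and Rora (0.0784, 0.141 and 0.41).

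Transcription factors that mark hypothalamic nuclei lay on the other side of the median. Of 18 measured members none passed over all genes, 1, Fezf1, passed adjusted over the list alone, and 13 lay above the median of all genes. Fezf1, a marker of the ventromedial nucleus, measured 2.15 ± 0.158 and 3.28 ± 0.0213 RPKM (log2 change 0.63, SE 0.145, limma adjusted p = 0.0973). Nkx2-1, Lhx1 and Foxb1 had log2 changes of 0.71, 0.67 and 0.56, with limma adjusted p of 0.165, 0.134 and 0.206. The list median was 0.29 (camera adjusted p = 2.69e-07; adjusted p = 0.578 with an estimated correlation). Without the filter on low values the median of the hypothalamic transcription factors was 0.07, with camera passed, and with a mean RPKM of at least 5 fewer than 5 members were left and the list was not tested.

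**Figure D2:**
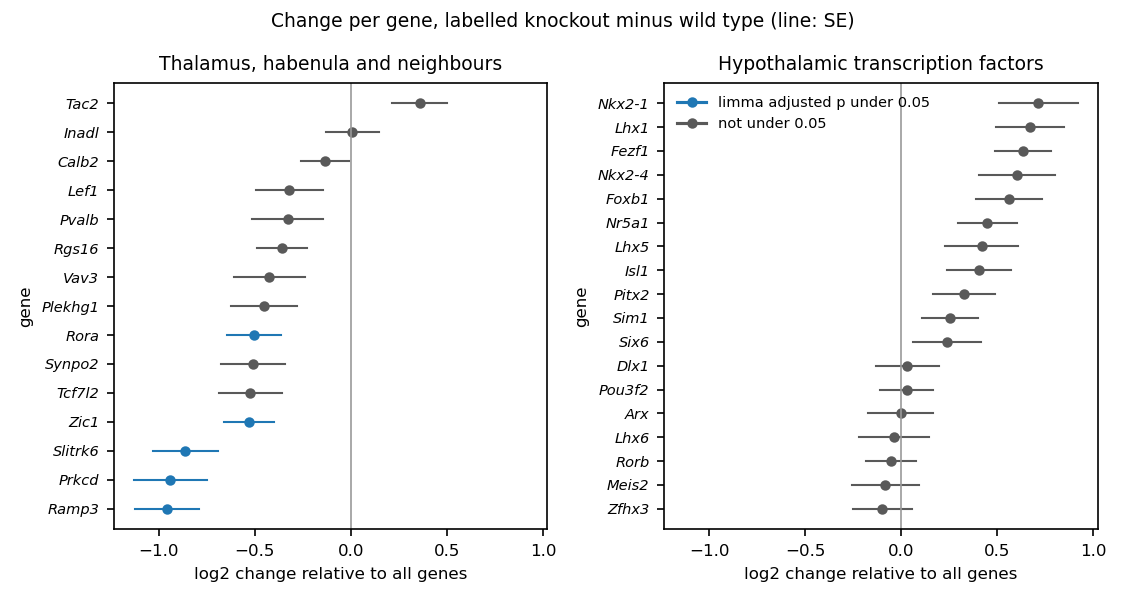
Log2 change relative to all genes (x axis, labelled knockout minus wild type) of each measured member of the thalamus list (left) and of the hypothalamic transcription factors (right). Lines are the SE from limma, and blue marks an adjusted p under 0.05. The list medians were -0.45 and 0.29.

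Genes of oxidative phosphorylation, the respiratory chain of mitochondria, were lower as a group. Of 55 measured members, 3 fell over all genes and 32 adjusted over the list alone, none rose, and 52 lay below the median of all genes. As in every list, counts over the list alone refer to the values as deposited and include the shift of all genes (median log2 change -0.12). Of all 11535 tested genes, 1773 were lower at unadjusted p under 0.05 in limma without overlap. Ndufa1 fell from 4.04 ± 0.547 to 2.02 ± 0.268 RPKM, Ndufs3 from 6.89 ± 0.252 to 4.34 ± 0.72 RPKM, both subunits of complex I, and Sdhb, a subunit of succinate dehydrogenase, from 19.9 ± 0.613 to 13.5 ± 0.491 RPKM (limma adjusted p 0.0183, 0.0468 and 0.0497). Also passing over the list alone were Atp5j, Ndufb7, Uqcrfs1, Ndufb8, Ndufa4, Ndufv1, Atp5e, Cox5a, Ndufv2, Uqcrh, Ndufb2, Ndufa9, Atp5f1, Sdhd, Cox8a, Ndufa8, Ndufb10, Ndufa7, Atp5g1, Ndufb5, Uqcrc1, Cox4i1, Ndufa10, Cox7b, Cox6a1, Ndufa3, Atp5b, Cox7a2 and Ndufs6. Over the list the median was -0.23 (camera adjusted p = 7.69e-13; adjusted p = 0.578 with an estimated correlation).

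Cytosolic ribosomal protein genes behaved alike in size. Of 51 measured members, 2 fell over all genes and 26 adjusted over the list alone, none rose, and 48 lay below the median of all genes. Rpl13a fell from 25.3 ± 0.656 to 17.1 ± 0.803 RPKM and Rps28 from 6.56 ± 1.39 to 3.7 ± 1.03 RPKM (limma adjusted p 0.0453 and 0.0465). Also passing over the list alone were Rpl9, Rps5, Rps19, Rplp1, Rps12, Rpl23, Rps4x, Rps2, Rpl11, Rpl5, Rps8, Rps14, Rps9, Rpl12, Rps11, Rplp0, Rpl13, Rps20, Rpl6, Rpl19, Rpl8, Rps3, Rpl24 and Rpl10. Many ribosomal protein genes have processed pseudogenes with shared reads, so single values are uncertain. For the list the median was -0.21 (camera adjusted p = 3.2e-13; adjusted p = 0.398 with an estimated correlation).

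Heat shock and unfolded protein response genes, which encode chaperones, were lower too. Of 28 measured members, 2 fell over all genes and 12 adjusted over the list alone, and none rose. Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, fell from 5.98 ± 1.13 to 3.29 ± 0.232 RPKM, and Hspa1b, an inducible HSP70 gene, from 3 ± 0.154 to 1.69 ± 0.316 RPKM (limma adjusted p 0.0228 and 0.0471). Hspa1b shares reads with its near-identical copy Hspa1a. Hsph1, Hspa5, Atf4, Hspe1, Manf, Hspa1a, Pdia6, Dnaja1, Hspb1 and Herpud1 passed over the list alone. The list median was -0.19 (camera adjusted p = 2.69e-07; adjusted p = 0.578 with an estimated correlation).

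Short genes were lower than long ones in the libraries labelled knockout, and the medians of these 3 lists were smaller in size with that trend removed. Spearman's correlation of log2 change and gene-model length, across 11223 genes that are not independent replicates, was 0.297. The trend differed in size between libraries of a group. Deviation and length correlated at -0.17 and -0.24 in wild type A and B, and at 0.29 and 0.09 in the libraries labelled knockout A and B. The median change was -0.09 for gene models up to 2103 bp and 0.06 for those above 4958 bp. With the trend removed from each library, the medians of oxidative phosphorylation, ribosomal protein and heat shock genes relative to all genes were -0.12, -0.10 and -0.15, from -0.23, -0.21 and -0.19, and all 3 lists still passed camera. With a mean RPKM of at least 5 the median of heat shock and unfolded protein response genes was -0.11. Malat1, Neat1 and Meg3, long noncoding RNAs kept in the nucleus and chosen after their values were seen, were higher in both libraries labelled knockout than in both wild-type libraries without passing (log2 changes 0.30, 0.65 and 0.42), as was Nktr (0.36), while Snhg11 overlapped between groups (0.19). None of the 7 single calls in the 3 lists held after rescaling (limma adjusted p from 0.0986 to 0.155) or after removal of the length trend (from 0.16 to 0.304), which also removes the shift of all genes, so these losses cannot be put down to length. The unshifted log2 changes of Ndufa1 and Sdhb were -0.85 and -0.54 as deposited, -0.73 and -0.41 after rescaling and -0.59 and -0.31 after removal of the length trend. Leaving out wild type A ended those of Ndufs3, Sdhb, Rpl13a, Sdf2l1 and Hspa1b (0.136, 0.367, 0.334, 0.223 and 0.201), wild type B those of Ndufa1, Ndufs3, Sdhb, Rpl13a, Rps28 and Hspa1b (0.11, 0.258, 0.311, 0.3, 0.318 and 0.123), and library A of those labelled knockout those of Ndufs3, Rps28 and Hspa1b (0.07, 0.0686 and 0.0795).

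Markers of several non-neuronal cell types lay slightly above the median of all genes and passed camera, with no member called over all genes. Medians were 0.12 for 28 oligodendrocyte and myelin genes (camera adjusted p = 0.0119), 0.15 for 15 genes of oligodendrocyte precursors (0.0227), 0.13 for 20 microglial genes (0.0264) and 0.18 for 7 genes of meninges and fibroblasts (0.00159). For ependyma and tanycytes, the cells that line the third ventricle, 12 genes had a median of 0.03 (camera adjusted p = 0.041). With an estimated correlation these adjusted p were 0.578, 0.619, 0.578, 0.398 and 0.578. Examples were Nkx6-2 (log2 change 0.59) and Ndrg1 (-0.28) of oligodendrocytes, Olig2 (0.42) and Matn4 (-0.29) of their precursors, Ctss (-0.23) and Ly86 (0.49) of microglia, and Islr (0.52) and Dcn (0.61) of fibroblasts. In the ependymal list, Nes and Gpr50 were higher (0.75 and 0.57) and Tmem212 lower (-0.47) adjusted over the list alone, and Frzb had 0.52. Calls of these lists ended without single libraries: oligodendrocytes without wild type A (0.208) or library A of those labelled knockout (0.158), precursors without wild type B (0.168) or that library (0.106), microglia likewise (0.311 and 0.283), and ependyma without wild type B (0.366), library A (0.446) or library B (0.101) of those labelled knockout. The ependyma and tanycytes call also ended with median-ratio scaling (0.129), quantile normalization (0.182) and no filter (0.525), that of the list microglia with quantile normalization (0.0586), a mean RPKM of at least 5 (0.366) and no filter (0.179), that of oligodendrocyte precursors with the length trend removed (0.0549) and no filter (0.115), and that of oligodendrocytes and myelin with no filter (0.179). With the replicate letter as a block the call of ependyma and tanycytes ended too. With a mean RPKM of at least 5 fewer than 5 members of the ependymal and meningeal lists were left.

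**Figure D3:**
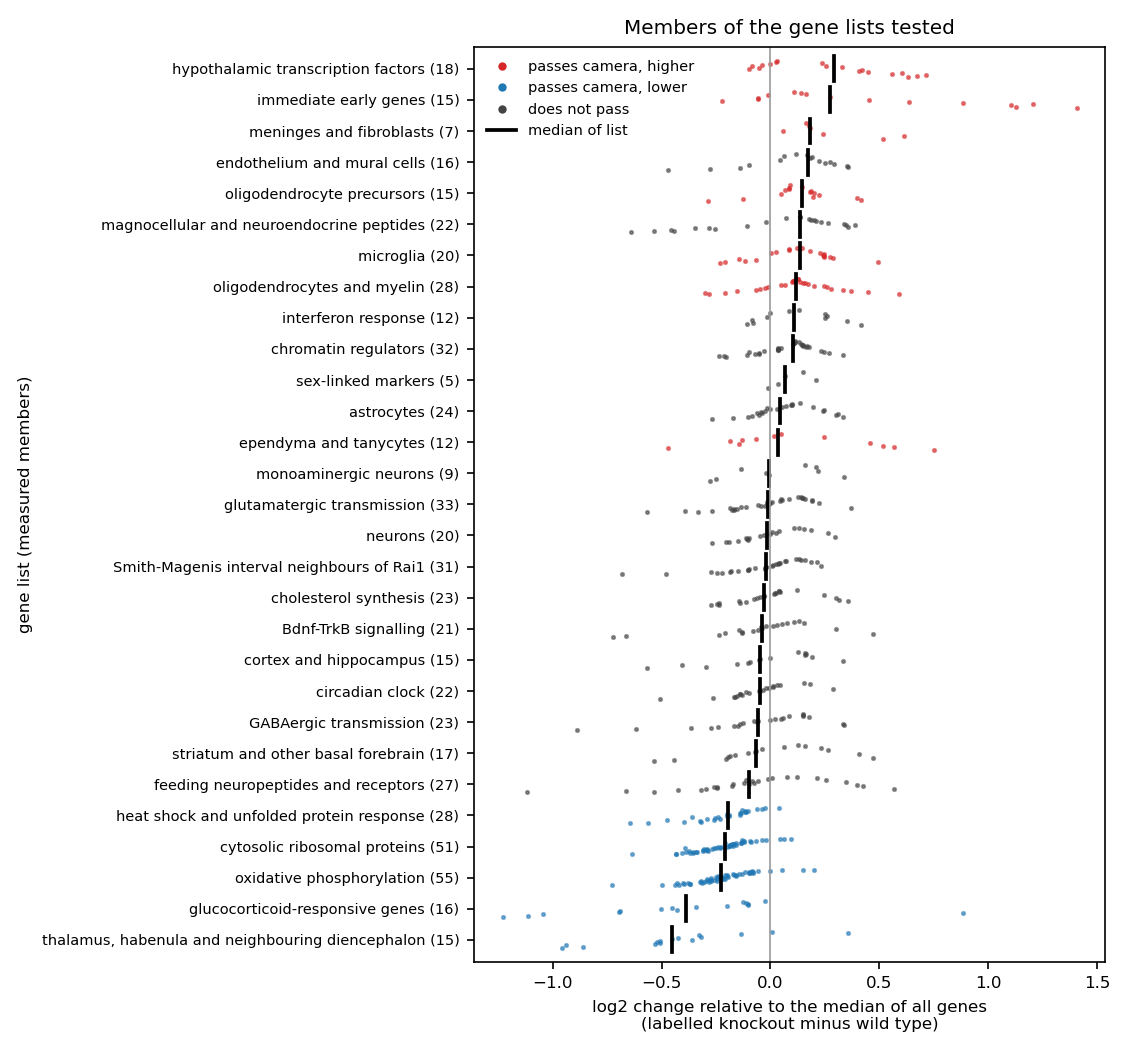
Log2 change relative to the median of all genes (x axis) for every measured member of the 29 lists tested (points), with the list median as a black bar. Red and blue lists passed camera at the preset correlation and lay above or below the other genes. Medians ran from -0.45 (thalamus) to 0.29 (hypothalamic transcription factors).

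Among neuropeptides of feeding and their receptors, 3 of 27 measured genes fell and none rose over all genes. These were Nts, Bdnf and Cck, the precursor of the satiety peptide cholecystokinin, which went from 11.3 ± 0.739 to 7.02 ± 0.191 RPKM (limma adjusted p = 0.0245). Adjusted over the list alone 8 fell and 1 rose: Adcyap1, Brs3, Cpe, Pmch and Htr2c joined the first 3, and Gpr50 was the 1 higher. The list had a median of -0.10 (camera adjusted p = 0.181). Of 22 magnocellular and neuroendocrine peptide genes, 2 fell over all genes and 5 adjusted over the list alone. Oxt, the precursor of oxytocin, went from 48 ± 7.34 to 28.6 ± 8.09 RPKM, and Tac1, the precursor of substance P, from 10.3 ± 0.518 to 6.44 ± 1.23 RPKM (limma adjusted p 0.0364 and 0.0399). Penk, Vip and Scg2 passed over the list alone. The list's median was 0.14, its mean -0.0017, and it did not pass camera (adjusted p = 0.685, tested as higher). The calls of Cck, Oxt and Tac1 ended with rescaling (limma adjusted p 0.105, 0.2 and 0.112) and without wild type A (0.0788, 0.226 and 0.0922). Those of Cck and Tac1 also ended without wild type B (0.258 and 0.238), and that of Tac1 without library A of those labelled knockout (0.055).

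Genes of synaptic transmission and the clock held few calls. In GABAergic transmission, 2 of 23 measured genes fell over all genes and 5 adjusted over the list alone. They were the receptor subunit genes Gabrd, from 2.36 ± 0.355 to 0.949 ± 0.441 RPKM, and Gabra4, from 12.6 ± 2.87 to 7.25 ± 0.25 RPKM (limma adjusted p 0.0235 and 0.0266), then Gabrg1, Gabrg2 and Gabra3. Its list median was -0.06 (camera adjusted p = 0.355). With the length trend removed the median was -0.15 and the list passed camera (adjusted p = 0.0235), as it did with voom weights; as deposited it had an adjusted p = 0.79 with an estimated correlation. In glutamatergic transmission none of 33 passed over all genes and 2 fell adjusted over the list alone, Slc17a7 and Shank3 (median -0.01, camera adjusted p = 0.73). The circadian clock list had 1 fall among 22 genes, Rora, which is also in the thalamus list, with a median of -0.05 (camera adjusted p = 0.194). Per2, Nr1d2 and Hlf had log2 changes of -0.27, -0.17 and -0.16 and did not pass. Among 9 monoaminergic genes none passed (median -0.01, camera adjusted p = 0.485, tested as higher), and the lowest p was that of Maob (log2 change -0.28). After rescaling, the calls of Gabrd and Gabra4 ended (limma adjusted p 0.132 and 0.119), as did those of Gabra4 and Rora without wild type B (0.42 and 0.41) and of Rora without wild type A (0.0672).

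The remaining lists did not pass camera as deposited. Medians and camera adjusted p were -0.03 and 0.967 for cholesterol synthesis, 0.11 and 0.0599 for the interferon response, 0.10 and 0.106 for chromatin regulators, -0.01 and 0.73 for neurons, 0.04 and 0.322 for astrocytes, 0.17 and 0.0841 for endothelium and mural cells, -0.07 and 0.843 for the striatum and other basal forebrain, and -0.05 and 0.734 for cortex and hippocampus. With the length trend removed the interferon response and the endothelial list passed camera (adjusted p 0.012 and 0.0473), as they did with voom weights. As deposited these lists had an adjusted p = 0.674 and 0.737 with an estimated correlation. In the endothelial list Slc2a1, the glucose transporter of the blood-brain barrier, fell from 20.9 ± 0.568 to 13.7 ± 0.418 RPKM (limma adjusted p = 0.0336). That call ended with rescaling (limma adjusted p 0.105) and without wild type A or B (0.277 and 0.234). Of the striatal list Tac1 fell, and Tac1 and Penk passed over the list alone. Of the cortical list Slc17a7, Mef2c and Lamp5 were lower adjusted over the list alone. In the other 5 lists no member passed either way, and their members of lowest p included Pmvk, Ifit1, Hdac4, Tubb3 and Gjb6 (log2 changes -0.24, 0.42, -0.20, -0.27 and -0.27).

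Among 31 measured neighbours of Rai1 in the Smith-Magenis interval, 1 fell, Tmem11, from 8.26 ± 0.132 to 4.53 ± 0.49 RPKM (limma adjusted p = 0.0126), and none rose. The list median was -0.02 (camera adjusted p = 0.422). Rasd1 and Srebf1, the measured genes next to Rai1 on either side, had log2 changes of -0.48 and 0.19 and did not pass (limma adjusted p 0.134 and 0.853). Rnf112 and Kcnj12 had -0.22 and -0.25. Lists with fewer than 5 measured members had no camera test: choroid plexus with 3 (Prlr -0.11, Clic6 0.23), pituitary with 4 (Tshb 1.23, higher adjusted over the list alone, and Crhr1 -0.16) and blood with 3 (Alas2 0.87 higher and Snca -0.42 lower adjusted over the list alone). The sex-linked list of 5 measured genes had a median of 0.07 (camera adjusted p = 0.422). Xist, which is transcribed from the inactive X chromosome, was present in all 4 libraries (11.6 and 9.74 RPKM in wild type, 15 and 8.56 RPKM in the libraries labelled knockout), and Eif2s3x, Kdm6a, Ddx3x and Kdm5c had log2 changes of -0.01, 0.03, 0.07 and 0.15. Of the Y-linked genes, Eif2s3y and Kdm5d were listed at 0 in each library, Ddx3y had 1 read in wild type B and 1 in library B of those labelled knockout, and Uty had 1 read in each wild-type library.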

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

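The fits with the length trend removed and with voom weights were chosen after seeing the data, the others before. The number of called genes depended on the fit: without a filter on low values (19232 genes tested) 0 genes were higher and 0 lower, and with a mean RPKM of at least 5 (5495 genes) 278 were lower. Median-ratio scaling left 6 lower genes (46.2% of 13 calls, against 91.6% of 107), quantile normalization 4, no mean-variance trend 41 and removal of the length trend 9; this last fit also centres the libraries and tests 11223 genes, so its count is not an effect of length alone. At unadjusted p under 0.05 without overlap, 131 genes were higher and 1773 lower. Of all tested genes, 47.9% had no overlap between groups, where 33.3% is the chance for a single gene. All genes share the same libraries, and the shift of all genes (median log2 change -0.12) can raise that share. The excess over 33.3% is therefore no measure of the number of changed genes. Leaving out 1 library each gave 12 to 49 higher and 41 to 1097 lower genes, with the lone library of a group assumed to vary like the other group. As a paired fit with the replicate block, 60 genes were higher and 904 lower and 11 lists passed; the labels do not pair A with A, and A minus B correlated between groups at 0.248 across genes. Camera with an estimated correlation called 0 lists and fry 0 in 1 direction (10 with fry for mixed directions, 4 of them among the 12 that passed camera), and leaving out 1 library gave 8 to 13. For glucocorticoid-responsive genes the estimated correlation was -0.027, below the preset 0.01, yet the camera adjusted p was 0.398. With 2 residual degrees of freedom, the loss of calls under an estimated correlation is therefore no measure of correlation between genes. With the length trend removed 14 lists passed and with voom weights 15, of which GABAergic transmission, the interferon response and endothelium were new in both. Lists of feeding, monoaminergic neurons and chromatin regulators passed only without some single library or filter setting, the clock and pituitary only without a filter, the striatum with a mean RPKM of at least 5, and astrocytes with that or quantile normalization. The fits also differed in the prior degrees of freedom they borrowed. These were 3.66 without a filter, 8.83 with quantile normalization and 10.6 with median-ratio scaling. The main fit had 15.3 and the fit with a mean RPKM of at least 5 had 60.8. Voom weights had 25.4 but called fewer genes than the main fit. What caused the differences between fits was not tested.

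The log2 change of Rai1, 1.24 without the shift of all genes, kept its direction throughout and lost its call without a filter (1.24, adjusted p 0.403), with median-ratio scaling (1.36, 0.11), quantile normalization (1.38, 0.167), no mean-variance trend (1.24, 0.0749), robust eBayes (1.24, 0.477) and removal of the length trend (1.29, 0.136). Leaving out 1 library gave 0.65 to 1.82, called each time. Of 46 named called genes, 8 kept their call in every fit with a filter that tested them. These were Fos, Btg2, Junb, Nr4a1, Zbtb16, Tsc22d3, Nts and Plin4. Among them, Nr4a1, Zbtb16, Nts and Plin4 lay below a mean RPKM of 5 and were not tested with that filter. Calls of 46 were lost without a filter, 35 with quantile normalization, 33 with median-ratio scaling, 30 with the length trend removed, 19 without the trend of the variance, 10 with voom weights, 3 each with a pseudocount of 0.1 and robust eBayes, and 0 to 25 without 1 library. Of 2759 gene values under alternatives, 2267 stayed on their side of the threshold, 230 lost and 255 gained a call, and 7 changed sign. These belonged to 5 genes that did not pass and arose by leaving out 1 library: H2-D1 (-0.46 to 0.0055), Dcn (-0.0837 to 1.07), Clic6 (-0.0174 to 0.238), Srebf1 (-0.0716 to 0.203) and Xist (-0.297 to 0.478), on the unshifted scale. Under fry, which does not compare a list with other genes, the lists of oligodendrocytes and myelin (median 0.12) and of microglia (0.13) changed direction, with adjusted p of 0.922 each. With the depth at hand the median gene had 643 reads per library, so counting error matters mainly for low genes.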

Other observations

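Genes of this paragraph stand in none of the 32 fixed lists and were chosen after their values were seen. Of them, Ntng1 is also in the second thalamus list used below, which was written before its value was seen. Calb1, which encodes the calcium-binding protein calbindin, fell from 16.9 to 9.85 RPKM, Ntng1, an axon guidance gene, from 12.6 to 8.3 RPKM, and Gbx2, a transcription factor of the developing thalamus, from 1.82 to 0.653 RPKM (limma adjusted p 0.0189, 0.0465 and 0.029). Klf15 and Fam107a, both known to be induced by glucocorticoids, fell from 11.1 to 7.35 and from 53 to 35.7 RPKM (limma adjusted p 0.049 and 0.036). After median-ratio scaling none of these 5 calls held (limma adjusted p 0.0541 for Calb1, 0.163 for Ntng1, 0.11 for Gbx2, 0.149 for Klf15 and 0.112 for Fam107a), and Klf15 was called in 6 and Ntng1 in 8 of 15 alternatives. Of the clustered protocadherins, adhesion molecules that give neurons their identity, 20 of 20 measured Pcdhb genes and 18 of 20 Pcdhg genes lay above the median of all genes, with medians of 0.23 and 0.26. None of them was called, and paralogs of these clusters share reads. Of the 107 called genes, 74 stand in no list.

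Of the tests below, the 3 on Rai1, those of length and that of time of day were chosen after the results were seen. Rai1 was higher in both libraries labelled knockout, by a log2 of 1.35, against the label. The 10 measured genes on either side had a median log2 change of -0.0219 (SD 0.164), which argues against a change of the whole neighbourhood. An exchange of the labels of the 2 groups would turn the direction of Rai1 and of every other gene and stays open, since no other value in the table depends on the genotype alone. Reads from exons outside the deleted part could also raise the level, and the 1 value per gene leaves that open. A response of the remaining gene to deletion was not tested.

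Thalamic markers were lower and hypothalamic transcription factors higher, with medians of -0.45 and 0.29. After removal of the length trend the medians were -0.51 (bootstrap 95% interval -0.62 to -0.202) and 0.28 (-0.00614 to 0.499), which argues against transcript length as the whole cause for the thalamic markers and leaves it open for the transcription factors. These intervals are over the 15 and 18 genes of the lists. The genes share the same 4 libraries, so the intervals do not measure the spread between libraries. Second lists, written after the pattern but before the values of their genes were seen, gave medians of -0.16 for the thalamus (8 of 9 below the median of all genes) and 0.02 for the hypothalamus (10 of 18 above). The thalamus value lay in the range set beforehand for a smaller share of thalamus in the dissected tissue. The hypothalamus value lay between the bounds set for and against it. A smaller share of thalamus therefore cannot be told apart from a change within cells, and the dissection is not described per library. An effect of genotype stays open and was not tested.

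Immediate early genes were higher and glucocorticoid-responsive genes lower. With the length trend removed, all measured members had medians of 0.25 (bootstrap 95% interval 0.0905 to 1.13) and -0.29 (-0.699 to -0.122), from 0.27 and -0.39. Both intervals kept the sign of their median. For the glucocorticoid-responsive genes this argues against length as the whole cause. The lower end for the immediate early genes, 0.0905, fell short of the margin set for this test, which leaves length open for them. These intervals, too, are over genes that share the same 4 libraries. If the share of thalamus drove their called members, these would follow thalamic markers between the 2 libraries of a group. The observed over expected difference was 0.0833 for glucocorticoid-responsive and 0.136 for immediate early genes, with bootstrap 95% intervals of -0.339 to 1.1 and -0.154 to 0.698. Called genes were picked partly for a small spread within groups, which itself lowers this ratio. With 2 libraries per group the ratio therefore leaves the share of thalamus open for both sets. Collection at another time of day was tested by Dbp, Per2, Per3, Nr1d1, Ciart and Tef minus Arntl (-0.21, SE 0.168), which does not decide it. Handling before collection, corticosterone levels and genotype were not measured separately and stay open.

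The 4 libraries form only 3 splits into 2 and 2, too few for a share under 0.05. The real split called 107 genes and the highest of the others 3, so no other split reached the real count.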
